A study of Mus musculus with 6 samples.

How the data were processed

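RNA was measured in 6 samples of G1E-ER-GATA-1 cells, a mouse erythroid progenitor line that lacks GATA-1 of its own and carries GATA-1 fused to the ligand-binding domain of the oestrogen receptor, so that oestradiol switches the factor on. Per the labels' protocols, the cells received siRNA by nucleofection at 0 h and again at 24 h, oestradiol was added at 24 h, and cells were collected at 48 h. The siRNA was either non-targeting (control, 3 samples) or directed against Mi2β (3 samples), the ATPase that the Chd4 gene encodes. The labels do not say that the 3 samples of a group came from separate cultures, so p-values measure only the spread between these samples, which may be technical.

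Total RNA was labelled with Cy3 from 0.1 µg per sample and hybridised to 1-colour Agilent arrays, 1 sample per array. The deposited scanner values are spot intensities on a linear scale, made with Agilent Feature Extraction 10.7.3.1 per the file headers. The software had subtracted the background and replaced signals not above the negative controls with a small positive value, and the intensities were not normalized between arrays. Per the submitters' processing notes, Feature Extraction and limma were used, with the design and settings of the fit not given in the sources used here. The authors' deposited value table holds the same intensities rounded to 2 decimals: 100% of its values lay within 0.005 of the scanner's processed signal, or within its printed precision. Its column medians were 21.23, 16.95 and 20.92 for control replicates 1 to 3 and 25.9, 36.93 and 17.83 for knockdown replicates 1 to 3, so its scale is linear, it is not centred, and no direction is open.

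Each array had 62976 spots. Control spots and spots with an outlier flag were left out, spots of the same probe were averaged on the log2 scale, and 55681 probes remained. The main values are log2 of the processed signal minus the array's 75th percentile. Probes well above background on at least 3 of the 6 arrays were kept (31895 probes, of which 42 were left out because spots with an outlier flag left no value). The probe with the highest mean over the 6 arrays stands for its gene. In no changed gene did probes pass the test in opposite directions. Gene names are those of the array design, updated through accessions in the RefSeq gene table of GRCm38.p6: 27509 of 29150 probes with a RefSeq accession matched and 2017 names changed. The tests covered 22133 features, here called genes, of which 13110 have a gene symbol and 9023 are named by a clone, accession or predicted transcript. Probe coordinates are those of the file headers' build, mm9 (NCBI build 37). No genome of that build was used here, so the exon or untranslated region under a probe is not given.

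The knockdown was compared with the control by limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, no covariate), with Benjamini-Hochberg adjustment over all genes and a threshold of 0.05 on the adjusted p. "Rose" and "fell" are used of genes past that threshold. A further count required a change of at least 1 on the log2 scale. Values are given as the log2 change, knockdown minus control, with its standard error from 3 arrays per group. Where a gene was not well above background on any array of a group, on any of its probes, only a bound is given, "at least N-fold": the detected group's mean against the other group's mean of, per array, the higher of the gene's own value and the lowest signal of any probe well above background. That bound holds for the main values only. Under another background correction the change can lie below it, as for Cth with normexp (1.17 on the log2 scale).

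Before the data were examined, 27 gene lists were fixed from general knowledge of erythroid cells and of NuRD, with the rule for the genes named in the text. The rule takes Chd4, the 12 largest rises and 12 largest falls among changed genes with a gene symbol and non-overlapping groups (chance gives 10% of genes such groups), up to 4 members of each list by size of change, and a fixed set of erythroid and NuRD genes. A few genes that the rule takes are not reported here, and counts of genes examined singly include them. Other genes are named only where 5 or fewer members of a list rose, or 5 or fewer fell, or in a pair or family singled out in the closing part, and were chosen after their values were seen. Each list was tested with limma's camera at a preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 27 lists, and again with an estimated correlation and with fry. In 3 lists some members have only a bound, and with these at their bound all 3 medians stayed the same. In the haem list, the older name given for the haem transporter Slc48a1 matched Hrg, another gene, which was kept because the lists were fixed. The fit was tested on simulated data with the means and spreads, not the correlation, of the same 22133 genes, 200 changed. It recovered 2.99%, 41.8% and 83.3% of genes changed 1.5-, 2- and 4-fold, and 1 of 86 calls was false. The set test called the 1 shifted and 0 of 26 unshifted lists, with correlated lists untested.

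All 6 arrays lay on 1 slide and were scanned in 1 session. Slide row 1 held replicates 1 and 2 of both groups and row 2 held replicate 3 of both. Alternatives were normexp on the mean and background signals (offset 50) followed by quantile normalization, quantile normalization of the processed signal, scaling to the array median, the authors' deposited value table, a floor at the negative control level, no detection filter, detection on all 6 arrays, the mean over a gene's detected probes, keeping spots with an outlier flag, an intensity trend in eBayes, array weights, treat with a 1.2-fold minimum, the replicate number as a block, and each array left out in turn. Parentheses give the lowest and highest adjusted p over the 6 omissions for calls lost with arrays left out. For calls lost in other settings they cover the genes and settings named. Settings named as ending a call exclude the replicate block, whose effect is given with the other alternatives. A slide row block and row 1 alone were added after seeing the data. So few arrays limit the precision: the median standard error of a log2 change was 0.15.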

Results

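Gene expression was measured in G1E-ER-GATA-1 cells given an siRNA against Mi2β or a non-targeting siRNA, with GATA-1 switched on by oestradiol for 24 h. Each group had 3 arrays. Mi2β, encoded by Chd4, is the ATPase of NuRD, a complex that remodels nucleosomes and removes acetyl groups from histones. The comparison asks which transcripts depend on Mi2β while these cells mature. Between 53.1% and 56.5% of probes were well above background on the control arrays. The shares on the knockdown arrays were 61.3%, 74.0% and 48.5% for replicates 1 to 3. The negative control spots had a mean signal of 27.8 to 28.7 on the control arrays and of 29.2 to 34.2 on the knockdown arrays. Gene values correlated at 0.987 to 0.994 within groups and at 0.980 to 0.987 between groups, across genes, which are not independent replicates. The first principal component held 46.3% of the variance and separated the groups.

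**Figure D1:**
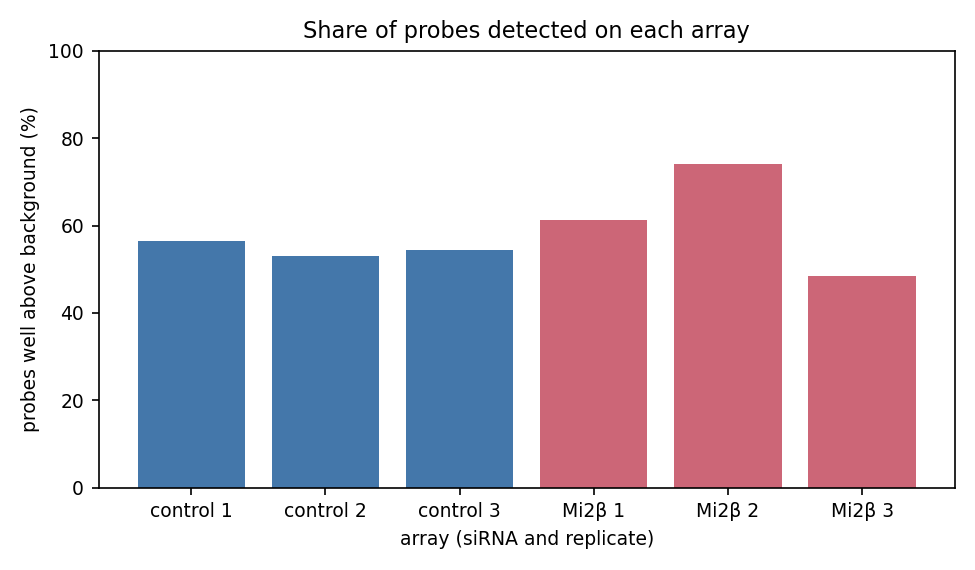
Bars give the percentage of probes well above background on each array, 3 control siRNA arrays in blue and 3 Mi2β siRNA arrays in red. Knockdown replicate 2 stands highest at 74.0% and knockdown replicate 3 lowest at 48.5%.

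The siRNA target was lower on every knockdown array than on any control array. Chd4 was at 5.89 ± 0.13 (SD, n = 3) on the control arrays and at 4.59 ± 0.04 (SD, n = 3) on the knockdown arrays, in log2 units relative to the array's 75th percentile. It fell by 1.31 on the log2 scale (SE 0.10), which is 2.48-fold lower, with an adjusted p = 0.00161 by limma. With the slide row as a block the change was -1.31 (adjusted p = 0.00391) and within row 1 it was -1.36 (adjusted p = 0.027), with adjusted p from 1.93e-05 to 0.027 over 21 alternatives. Its probe lies on chromosome 6 at 125080458 to 125080517 (mm9). Of 14 measured other NuRD subunits, 0 rose by limma (1 at an unadjusted p under 0.05) and 0 fell by limma (2 at an unadjusted p under 0.05), and adjusted over the list alone 0 rose and 0 fell. Their log2 changes included Chd3 at 0.07, Mta1 at -0.29, Mta2 at -0.33, Mta3 at -0.01, Hdac1 at 0.10, Hdac2 at -0.04, Mbd2 at -0.36, Mbd3 at 0.22 and Gatad2a at 0.44, none past the threshold. Under alternatives calls were gained (adjusted p range over 21 alternatives) by Gatad2a with normexp, quantile normalization, the filter of all 6 arrays, an intensity trend or array weights (0.0079 to 0.818), Mbd2 with the filter of all 6 arrays, an intensity trend or array weights (0.0227 to 0.878) and Mta2 with normexp, an intensity trend or array weights (0.0304 to 1.0). The list did not pass the set test (median -0.01, camera adjusted p = 0.913; adjusted p = 0.958 with an estimated correlation), nor with the row block (0.909) or within row 1 (0.183).

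With Mi2β knocked down, similar numbers of transcripts rose and fell, and the large changes were mostly rises. In all, 1105 genes rose and 1010 fell (854 and 782 with a gene symbol), out of 22133 tested by limma, against a median change of -0.03 over all genes. At least 2-fold, 560 genes rose and 198 fell, so that 73.9% of these were rises. Rises made up 51.1% of those at or above the median control signal of all genes tested and 86.6% of those below it. At least 8-fold, 84 genes rose and 0 fell by limma (0 at an unadjusted p under 0.05). Of the genes that rose at least 2-fold, 92 were well above background on no control array, and 3 of those that fell were well above background on no knockdown array.

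**Figure D2:**
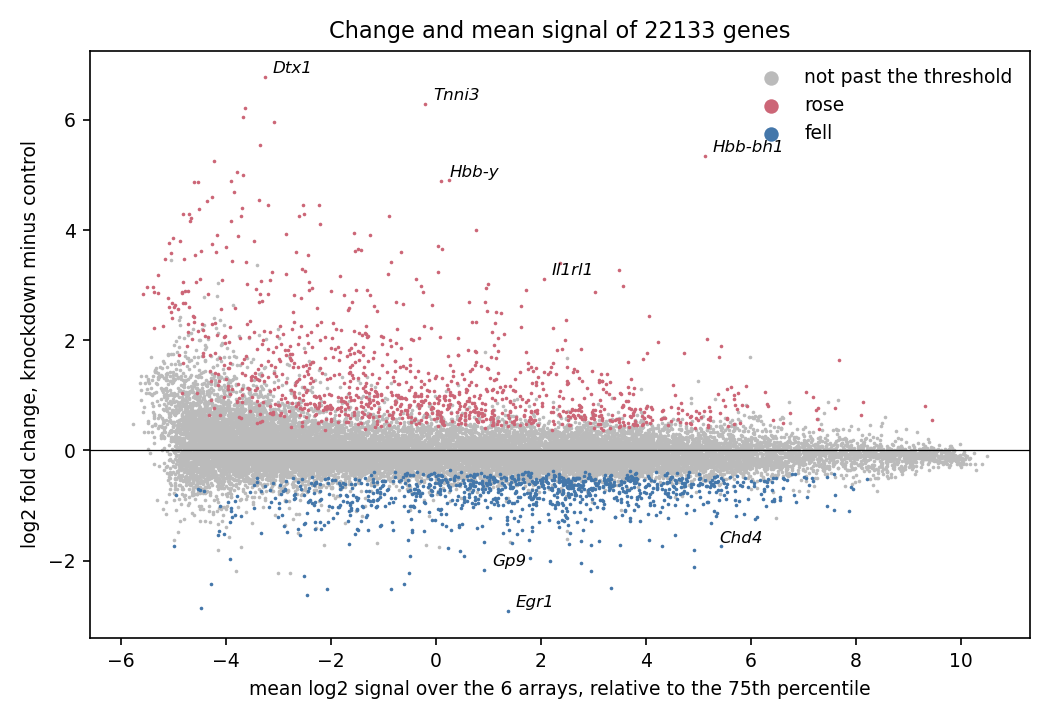
Each point is 1 of 22133 genes, with its mean log2 signal over the 6 arrays (relative to the 75th percentile) on the x axis and its log2 fold change, knockdown minus control, on the y axis. Red points rose (1105), blue points fell (1010) and grey points did not pass the threshold; genes not well above background in a group are drawn at their fitted value, and named points include Hbb-bh1 among the rises and Egr1 among the falls.

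Of the 12 largest rises with a gene symbol, 8 were of transcripts not well above background in the control cells. Dtx1, a ubiquitin ligase of the Notch pathway, was at least 30.2-fold higher (adjusted p = 8.11e-05) and not well above background on any control array. The same held for the tyrosine kinase gene Ptk6 (at least 25.9-fold), Pnma5 (at least 19.2-fold), Palm3 (at least 18.5-fold), Cfap43 (at least 17.6-fold), Ecel1 (at least 12.3-fold), Mfap5 (at least 10.1-fold) and Ssh3 (at least 9.17-fold). The adjusted p of these 8 genes ranged from 1.36e-05 to 0.00263. Their fitted changes were 1.59 to 2.92 on the log2 scale with normexp, whose offset compresses dim signals, so these folds depend on the background correction. Tnni3, which encodes cardiac troponin I, rose by 6.28 (SE 0.22, adjusted p = 0.000154), and P2rx7, an ATP-gated ion channel, was 29.9-fold higher (adjusted p = 7.61e-05).

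The largest falls were smaller. Egr1, an immediate early transcription factor, fell by 2.92 (SE 0.10, adjusted p = 0.000134). Among the other large falls were Ptgir (-2.62, SE 0.14), the prostacyclin receptor gene, Ugdh (-2.52, SE 0.18), Zcwpw1 (-2.51, SE 0.16), Adgrg1 (-2.50, SE 0.19) and Afmid (-2.42, SE 0.16). Scube2 fell by 2.19 (SE 0.19) and the platelet glycoprotein gene Gp9 by 2.18 (SE 0.24). Atp8b1, a phospholipid flippase, was at least 3.85-fold lower (adjusted p = 0.00638) and not well above background on any knockdown array, with a fitted change of -0.71 with normexp. Nanog fell by 2.28 (SE 0.20, adjusted p = 0.00223), a call that the mean over its probes ended (-0.80, adjusted p = 0.172; adjusted p from 3.38e-09 to 0.172 over 21 alternatives). Ccdc173 fell by 2.43 (SE 0.44) and was well above background on 1 of 3 knockdown arrays. With normexp the changes were smaller, with Ccdc173 at -0.61, Nanog at -1.28, Ptgir at -1.50 and Zcwpw1 at -1.59. Single arrays decided some of these calls (adjusted p range with arrays left out in turn): Ccdc173 (0.0051 to 0.107) without control replicate 1, 2 or 3 or knockdown replicate 1. Lost as well were the calls of Ccdc173 with no detection filter or row 1 alone (0.0713 to 0.102) and Atp8b1 with row 1 alone (0.0665).

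The number of changed genes depended on the arrays used. It was 1063 without control replicate 1 (679 rose), 1150 without control replicate 2 (734 rose), 813 without knockdown replicate 1 (557 rose) and 1163 without knockdown replicate 2 (701 rose). With the slide row as a block 1801 genes changed (770 at least 2-fold), and within row 1 alone (2 arrays per group) 720 did (662 at least 2-fold); row 2 held 1 array of each group, which gives no test. The row block ended 22 of 138 calls of the genes examined singly besides Chd4, those of Abcb10, Atg3, Ccnb2, Cd68, Cdc45, Ctsb, Ddx58, E2f2, Glb1, H2-T10, H2aw, Ifit2, Ift57, Ift80, Itgb1, Klf4, Psmb9, Selp, Slc25a38, Tal1, Tigar and Vim. With array median scaling 496 genes rose and 335 fell at least 2-fold, so that 59.7% were rises, and 75 of the 138 calls ended. Of these genes Bax (to 0.37), Calr (to 0.44), Cd68 (to 0.29), Cdkn1a (to 0.35), Ddx58 (to 0.20), Glb1 (to 0.24), H2-T10 (to -0.69), H2aw (to 0.36), Icam4 (to 0.25), Klf4 (to 0.27), Lyl1 (to 0.39), Neu1 (to 0.27) and Nr2c1 (to 0.29) moved by over 1.5 times. Without the detection filter 62 of those calls ended, with treat 59, and within row 1 73.

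The embryonic globin genes rose strongly, and 4 of 5 adult globin probes did not pass the threshold. Hbb-bh1 rose by 5.34 (SE 0.12, adjusted p = 3.38e-05), a 40.6-fold change, and Hbb-y by 4.89 (SE 0.17, adjusted p = 0.00015). Hba-x, well above background on 2 of 3 control arrays, rose by 3.54 (SE 0.20, adjusted p = 0.000619), or by 1.76 with normexp. These genes' probes lie on chromosome 7 at 110990209 to 110990268 and 111000268 to 111000327, and on chromosome 11 at 32177668 to 32177727 (mm9). The adult globin probes gave log2 changes of 0.09 for Hba-a1, -0.09 for Hba-a2, 0.01 for Hbb-b2 and -0.19 for Hbb-bs, none past the threshold, and between -0.42 and 0.22 over 3 other scalings, under which the signs varied (adjusted p from 0.156 to 0.866). Hbb-bt, named Hbb-b1 by the array design, rose by 0.81 (SE 0.11, adjusted p = 0.00933), and not with array median scaling (0.58, adjusted p = 0.596) or within slide row 1 (adjusted p = 0.085), with adjusted p from 0.000287 to 0.596 over 21 alternatives. Globin genes are close copies, so their probes may share signal. Adult probes had control signals of 109590 to 561030, where response was not tested. Of 13 measured embryonic and adult globins and globin silencing factors, 5 rose and 0 fell by limma (2 at an unadjusted p under 0.05). Adjusted over the list alone 5 rose and 1 fell. Its rises were Hbb-bh1, Hbb-y, Hba-x, the adult globin Hbb-bt and the silencing factor Nr2c1 (0.52, SE 0.12), named after its value was seen. The list lay higher (median 0.22, from -0.01 to 0.31 over 21 alternatives; camera adjusted p = 0.00227; adjusted p = 0.672 with an estimated correlation), with camera adjusted p = 0.00337 with the row block and 0.0607 within row 1 (median 0.21), though its median turned to -0.01 with array median scaling, where the median of all genes was -0.27. Its mean was 1.14. Row 1 alone ended its call (adjusted p from 9.2e-11 to 0.0607 over 21 alternatives). Only 3 rose and none fell without knockdown replicate 1. Calls were lost for (adjusted p range) Nr2c1 (0.0682 to 0.188) with any array left out and Hbb-bt (0.0293 to 0.0545) without knockdown replicate 1. Nr2c1 also lost its call with array median scaling, no detection filter, treat or row 1 alone (0.117 to 0.76).

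**Figure D3:**
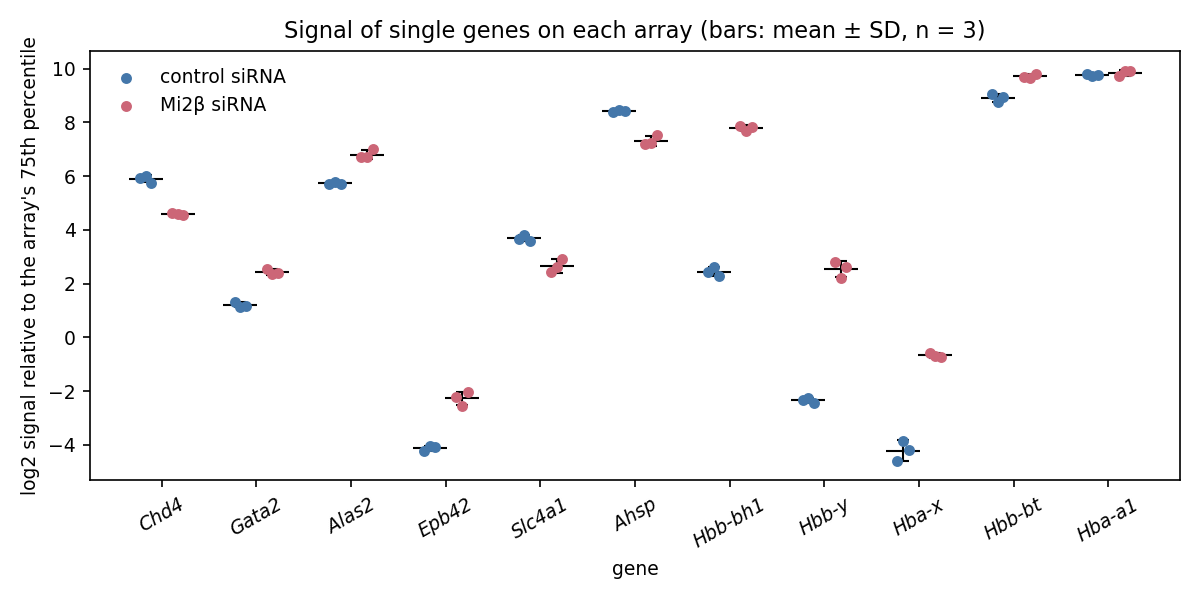
Points give the log2 signal of single genes on each array relative to the array's 75th percentile, control siRNA in blue and Mi2β siRNA in red, with mean ± SD of 3 arrays. Hbb-bh1, Hbb-y, Hba-x, Gata2, Alas2 and Epb42 lie higher on every knockdown array than on any control array, and Chd4, Slc4a1 and Ahsp lower.

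Genes listed as activated by GATA-1 during red cell maturation moved in both directions. Of 39 measured members of that list, 5 rose and 12 fell, and adjusted over the list alone 6 rose and 18 fell. Bcl2l1, a survival gene, fell by 1.73 (SE 0.17, adjusted p = 0.00338). Also lower were Ahsp (-1.11, SE 0.12), the alpha-globin chaperone gene, Slc4a1 (-1.04, SE 0.15), the anion exchanger gene, and the transcription factor genes Nfe2 (-0.78, SE 0.14) and Tal1 (-0.50, SE 0.11). Epb42, encoding protein 4.2 of the red cell membrane, rose by 1.85 (SE 0.15, adjusted p = 0.00176), or by 0.67 with normexp. Hbb-bt, a member here too, rose. Alas2, the erythroid enzyme that starts haem synthesis, rose by 1.06 (SE 0.12, adjusted p = 0.00467), a call that array median scaling ended (0.83, adjusted p = 0.309; adjusted p from 0.000103 to 0.309 over 21 alternatives). Klf1 at 0.27, Zfpm1 at -0.20 and Gata1 at -0.41 (adjusted p = 0.115) did not pass. A call was gained by Gata1 with an intensity trend or array weights (0.0199 to 0.823). Past the threshold too, and named after their values were seen, were Icam4 (0.48, SE 0.09) and Ubac1 (1.00, SE 0.10).

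The genes activated by GATA-1 lay lower (median -0.25, from -0.48 to -0.17 over 21 alternatives; camera adjusted p = 0.0191; adjusted p = 0.672 with an estimated correlation), with camera adjusted p = 0.0257 with the row block and 0.00204 within row 1 (median -0.28). That call ended without knockdown replicate 2 (0.206) and with normexp with quantile normalization (0.0931) or quantile normalization (0.204). Adjusted p spanned 0.000766 to 0.206 over 21 alternatives. Of its members, 4 rose and 4 fell without control replicate 1 or 2, 3 rose and 3 fell without knockdown replicate 1 and 4 rose and 5 fell without knockdown replicate 2. With arrays left out in turn, calls were lost for Tal1 (0.0786 to 0.173) and Icam4 (0.0613 to 0.109) with any array left out, Nfe2 (0.0242 to 0.109) with any array left out except knockdown replicate 3 and Slc4a1 (0.0126 to 0.0533) without control replicate 1 or 2 or knockdown replicate 1. Also lost were the calls of Nfe2, Tal1 and Icam4 with array median scaling, no detection filter, treat or row 1 alone (0.060 to 0.785) and Ubac1 with array median scaling or row 1 alone (0.0571 to 0.378).

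Red cell membrane and skeleton genes overlapped that list and lay lower. Of 25 measured members, 3 rose and 9 fell, and adjusted over the list alone 5 rose and 12 fell. Besides the shared members, the nucleoside transporter gene Slc29a1 (1.00, SE 0.11) rose, and the other rises were those of Epb42 and Icam4 (0.48). The list lay lower (median -0.28, from -0.52 to -0.23 over 21 alternatives; camera adjusted p = 0.0289; adjusted p = 0.672 with an estimated correlation), with camera adjusted p = 0.0452 with the row block and 0.00622 within row 1 (median -0.44). Its call ended without knockdown replicate 1 (0.0867) or knockdown replicate 2 (0.202) and with quantile normalization (0.0999), array median scaling (0.0735) or the filter of all 6 arrays (0.0597). Adjusted p spanned 0.00205 to 0.202 over 21 alternatives. Among its members 2 rose and 3 fell without control replicate 1 or knockdown replicate 1 and 2 rose and 4 fell without control replicate 2 or knockdown replicate 2. Other calls lost were those of Slc29a1 with array median scaling (0.373).

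Haem and autophagy genes changed singly. Of 27 measured haem synthesis and iron genes, 1 rose and 4 fell, and adjusted over the list alone 1 rose and 6 fell. The rise was that of Alas2, and the falls were Aco1 (-1.44, SE 0.15), the iron-responsive aconitase gene, Abcb10 (-0.89, SE 0.19), Alas1 (-0.81, SE 0.10), the form of the enzyme outside the red cell lineage, and Slc25a38 (-0.50, SE 0.10), the last named after its value was seen. The haem list did not pass the set test (median -0.10, camera adjusted p = 0.289; adjusted p = 0.766 with an estimated correlation), nor with the row block (0.371), and did within row 1 (0.0273). It passed with no detection filter (0.0339) or slide row 1 alone (0.0273). Adjusted p spanned 0.0273 to 0.804 over 21 alternatives. Of 27 measured autophagy and mitochondrial clearance genes, 0 rose by limma (2 at an unadjusted p under 0.05) and 2 fell, and adjusted over the list alone 0 rose and 2 fell. Those that fell were Foxo3 (-0.89, SE 0.17) and Atg3 (-0.51, SE 0.10), while Bnip3 at -0.74 and Atg7 at -0.46 did not pass. Calls were gained by Bnip3 with array weights (0.0449 to 0.647) and Atg7 with normexp, the filter of all 6 arrays or an intensity trend (0.0199 to 0.539). The autophagy list did not pass the set test (median -0.15, camera adjusted p = 0.0997; adjusted p = 0.675 with an estimated correlation), nor with the row block (0.0791), and did within row 1 (0.0029). It passed without knockdown replicate 3 (0.00387) and with no detection filter (0.00482) or slide row 1 alone (0.0029). Adjusted p spanned 0.0029 to 0.687 over 21 alternatives. Of the haem genes 1 rose and 2 fell with any array left out except control replicate 3. Of the autophagy genes none rose and none fell with any array left out except knockdown replicate 3 and none rose and 1 fell without knockdown replicate 3. Arrays left out in turn ended the calls of Slc25a38 (0.053 to 0.135) and Atg3 (0.0776 to 0.105) with any array left out, Abcb10 (0.0116 to 0.15) with any array left out except control replicate 3 and Foxo3 (0.0194 to 0.104) with any array left out except knockdown replicate 3. Further calls lost were those of Slc25a38, Foxo3 and Atg3 with array median scaling, no detection filter, treat or row 1 alone (0.0511 to 0.414), Abcb10 with array median scaling, no detection filter or treat (0.0654 to 0.141) and Alas1 with array median scaling or row 1 alone (0.0583 to 0.109).

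Genes that GATA-1 represses as progenitors mature went both ways. Of 22 measured members, 4 rose and 4 fell, and adjusted over the list alone 7 rose and 7 fell. Gata2, the GATA factor that GATA-1 replaces, rose by 1.22 (SE 0.10, adjusted p = 0.00199), though not with array median scaling (0.99, adjusted p = 0.145; adjusted p from 3.59e-05 to 0.145 over 21 alternatives). Also higher were Hdc (2.05, SE 0.15), the histidine decarboxylase gene, Cd44 (0.93, SE 0.18) and Lyl1 (0.62, SE 0.10). Fli1, a factor of the megakaryocyte branch, fell by 0.93 (SE 0.13), as did Runx1 (-0.93, SE 0.10), Ccnd2 (-0.65, SE 0.10) and Vim (-0.53, SE 0.11), these 3 named after their values were seen. Kit at 0.40, Myc at 0.51, Myb at -0.06 and Hhex at 0.03 did not pass. Calls were gained by Kit with normexp, an intensity trend or array weights (0.0129 to 0.875) and Myc with normexp, the filter of all 6 arrays, an intensity trend or array weights (0.0164 to 0.769). The list did not pass the set test (median 0.01, camera adjusted p = 0.763; adjusted p = 0.905 with an estimated correlation), nor with the row block (0.769) or within row 1 (0.783). Of its members 3 rose and 2 fell without control replicate 1, 2 rose and 1 fell without knockdown replicate 1 and 2 rose and 2 fell without knockdown replicate 2. Calls lost with arrays left out in turn were those of Vim (0.0355 to 0.131) with any array left out except control replicate 2, Cd44 (0.0426 to 0.13) without control replicate 2 or knockdown replicate 1, 2 or 3, Ccnd2 (0.0318 to 0.0703) without control replicate 1 or 2 or knockdown replicate 1 or 2, Lyl1 (0.0355 to 0.0872) without control replicate 1 or knockdown replicate 1 or 2 and Fli1 (0.0253 to 0.0632) without knockdown replicate 1. Lost as well were the calls of Cd44, Lyl1, Ccnd2 and Vim with array median scaling, no detection filter, treat or row 1 alone (0.0636 to 0.707) and Fli1 and Runx1 with array median scaling or row 1 alone (0.0501 to 0.0562).

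Among other chromatin remodellers and GATA-1 cofactors the changes were falls. Of 22 measured members, 0 rose by limma (0 at an unadjusted p under 0.05) and 3 fell, and adjusted over the list alone 0 rose and 3 fell. Those that fell were Cbfa2t3 (-1.09, SE 0.09, adjusted p = 0.00199), a corepressor gene, Brd3 (-0.60, SE 0.10) and Lmo2 (-0.49, SE 0.09), while Ezh2 at -0.42 did not pass. A call was gained by Ezh2 with normexp or an intensity trend (0.0337 to 0.854). With the mean over probes the change of Cbfa2t3 was -0.70. The list lay lower (median -0.29, from -0.52 to -0.20 over 21 alternatives; camera adjusted p = 0.00281; adjusted p = 0.672 with an estimated correlation), with camera adjusted p = 0.00322 with the row block and 0.0017 within row 1 (median -0.27). Its counts moved, and none rose and 1 fell with any array left out except control replicate 3. Arrays left out ended the calls of Lmo2 (0.0522 to 0.111) with any array left out and Brd3 (0.0414 to 0.0809) with any array left out except control replicate 3. Further losses were those of Brd3 and Lmo2 with array median scaling, no detection filter, treat or row 1 alone (0.0822 to 0.43).

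Mast cell and basophil genes lay higher. Of 17 measured markers, 7 rose and 1 fell, and adjusted over the list alone 9 rose and 2 fell. The interleukin-33 receptor gene Il1rl1 rose by 3.11 (SE 0.19, adjusted p = 0.000748), and the mast cell protease genes Mcpt1 (2.91, SE 0.10) and Mcpt4 (2.70, SE 0.10) rose too, the latter by 1.73 with normexp. Tpsab1, a tryptase gene, was at least 2.57-fold higher (adjusted p = 0.00445) and not well above background on any control array; its fitted change was 0.47 with normexp. Also past the threshold, and named after its value was seen, was Rab27b (-1.44, SE 0.10). The list lay higher (median 0.61, from 0.17 to 0.73 over 21 alternatives; camera adjusted p = 0.000125; adjusted p = 0.29 with an estimated correlation), with camera adjusted p = 0.000173 with the row block and 0.0017 within row 1 (median 0.52).

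Megakaryocyte genes lay lower as a group. Of 18 measured markers, 2 rose and 8 fell, and adjusted over the list alone 3 rose and 9 fell. The 4 with the largest changes were Gp9 (-2.18, SE 0.24), Plek (-1.73, SE 0.15), the integrin gene Itgb3 (-1.72, SE 0.17) and the platelet factor 4 gene Pf4 (-1.62, SE 0.14). The pair that rose was Treml1 (1.58, SE 0.11) and Selp (0.88, SE 0.19), named after their values were seen. The list lay lower (median -0.34, from -0.77 to -0.13 over 21 alternatives; camera adjusted p = 0.00981; adjusted p = 0.672 with an estimated correlation), with camera adjusted p = 0.00666 with the row block and 0.00884 within row 1 (median -0.54). With arrays omitted, 1 rose and 6 fell without control replicate 2 or knockdown replicate 1 or 2 and 1 rose and 7 fell without knockdown replicate 3. Calls were lost for Selp (0.028 to 0.132) with any array left out except control replicate 3. Calls also ended for Selp with normexp with quantile normalization (0.26, adjusted p = 0.0643), within a range of 0.00769 to 0.523 over 21 alternatives. Also lost were the calls of Selp with array median scaling, no detection filter, treat or row 1 alone (0.0649 to 0.523).

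Markers of the granulocyte and lymphocyte lineages gave scattered rises. Of 18 measured granulocyte and monocyte markers, 4 rose and 0 fell by limma (2 at an unadjusted p under 0.05), and adjusted over the list alone 4 rose and 2 fell. Those that rose were Tyrobp (2.29, SE 0.36, well above background on 1 of 3 control arrays), Fcgr3 (1.38, SE 0.25), Cebpe (1.36, SE 0.25, well above background on 2 of 3 control arrays) and Cd68 (0.53, SE 0.10). With the mean over probes Cd68 did not pass (0.85, adjusted p = 0.119; adjusted p from 0.00431 to 0.758 over 21 alternatives). That list did not pass the set test (median 0.10, camera adjusted p = 0.178; adjusted p = 0.672 with an estimated correlation), nor with the row block (0.167) or within row 1 (0.0825). Of 13 measured lymphocyte markers, 2 rose and 0 fell by limma (1 at an unadjusted p under 0.05), and adjusted over the list alone 3 rose and 1 fell. Those that rose were the kinase gene Lck (1.62, SE 0.09) and Gata3 (0.75, SE 0.13), while Vpreb1 at -1.40 did not pass. A call was gained by Vpreb1 with normexp, quantile normalization, array median scaling, the filter of all 6 arrays, an intensity trend, array weights, the slide row as a block or without knockdown replicate 2 or 3 (0.00082 to 0.165). The lymphocyte list did not pass the set test (median 0.01, camera adjusted p = 0.223; adjusted p = 0.672 with an estimated correlation), nor with the row block (0.257) or within row 1 (0.136). With normexp the sizes shrank, with Cebpe at 0.39 and Tyrobp at 0.78. Of the granulocyte and monocyte markers 1 rose and none fell without control replicate 2 or 3 or knockdown replicate 1 or 3, 2 rose and none fell without control replicate 1 and none rose and none fell without knockdown replicate 2. Of the lymphocyte markers 1 rose and none fell without control replicate 2 or knockdown replicate 1 and 1 rose and 1 fell without knockdown replicate 2 or 3. Calls ended by omitting an array were those of Fcgr3 (0.027 to 0.0886) with any array left out except control replicate 3, Cebpe (0.0296 to 0.0769) with any array left out except knockdown replicate 1, Cd68 (0.0489 to 0.14) with any array left out except control replicate 1, Gata3 (0.0267 to 0.0958) without control replicate 2 or knockdown replicate 1, 2 or 3 and Tyrobp (0.00741 to 0.0714) without control replicate 3 or knockdown replicate 1 or 2. Other calls lost were those of Cebpe, Cd68 and Gata3 with array median scaling, no detection filter, treat or row 1 alone (0.0589 to 0.758), Fcgr3 with array median scaling, no detection filter or treat (0.0515 to 0.071) and Tyrobp with row 1 alone (0.098).

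A few neuronal and muscle genes changed. Of 16 measured neuronal genes, 2 rose and 1 fell, and adjusted over the list alone 2 rose and 1 fell. The tubulin gene Tubb3 (2.01, SE 0.21) rose, Dcx was at least 2.87-fold higher (not well above background on any control array; fitted change 0.56 with normexp), and Chgb was at least 1.88-fold lower (not well above background on any knockdown array; fitted change -0.36 with normexp). The neuronal list did not pass the set test (median 0.10, camera adjusted p = 0.223; adjusted p = 0.675 with an estimated correlation), nor with the row block (0.167) or within row 1 (0.136). It passed with array median scaling (0.0292), higher than other genes with a median of -0.13 against -0.27 for all genes. Adjusted p spanned 0.0292 to 0.62 over 21 alternatives. Of 14 measured muscle genes, 2 rose and 1 fell, and adjusted over the list alone 4 rose and 1 fell. The rises were those of Tnni3 (6.28) and Tnnt1 (0.95, SE 0.14), and Tpm1 (-0.53, SE 0.09) fell, or -0.82 with the mean over its probes. The muscle list lay higher (median 0.33, from 0.10 to 0.48 over 21 alternatives; camera adjusted p = 0.0329; adjusted p = 0.672 with an estimated correlation), with camera adjusted p = 0.040 with the row block and 0.0163 within row 1 (median 0.44). Its call ended without control replicate 2 (0.108) or knockdown replicate 2 (0.163) and with normexp with quantile normalization (0.11), quantile normalization (0.149) or array weights (0.162). Adjusted p spanned 0.000209 to 0.163 over 21 alternatives. With normexp the change was smaller, with Tnnt1 at 0.58. Of the neuronal genes 1 rose and 1 fell without control replicate 2 or 3 or knockdown replicate 1 or 2. Of the muscle genes 2 rose and none fell without control replicate 1 or knockdown replicate 1 or 2 and 1 rose and none fell without control replicate 2. Omitted arrays ended the calls of Dcx (0.035 to 0.0944) without control replicate 2 or 3 or knockdown replicate 1 or 2, Tpm1 (0.0434 to 0.0911) without control replicate 1 or 2 or knockdown replicate 1 or 2 and Tnnt1 (0.0312 to 0.0502) without control replicate 2. Other settings ended the calls of Chgb with an intensity trend (-1.74, adjusted p = 0.0768), within a range of 1.41e-05 to 0.0768 over 20 alternatives. Further calls lost were those of Tpm1 with array median scaling, no detection filter, treat or row 1 alone (0.0802 to 0.381), Tnnt1 with array median scaling or row 1 alone (0.080 to 0.434) and Dcx with no detection filter or row 1 alone (0.0764 to 0.108).

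Cholesterol synthesis genes were lower together, with the lowest camera p of the 27 lists. Of 23 measured members, 0 rose by limma (0 at an unadjusted p under 0.05) and 7 fell, and adjusted over the list alone 0 rose and 12 fell. None of the 23 had a change above 0. Stard4, a sterol carrier, fell by 1.02 (SE 0.12, adjusted p = 0.0057), and the pathway enzyme genes Fdps (-0.92, SE 0.12), Idi1 (-0.88, SE 0.13) and Mvd (-0.82, SE 0.14) fell too. The list lay lower (median -0.46, from -0.69 to -0.37 over 21 alternatives; camera adjusted p = 1.0e-06; adjusted p = 0.672 with an estimated correlation), with camera adjusted p = 4.5e-06 with the row block and 9.37e-07 within row 1 (median -0.50). With arrays omitted, none rose and 3 fell without control replicate 2 or knockdown replicate 2, none rose and 2 fell without control replicate 1, none rose and 1 fell without knockdown replicate 1 and none rose and 4 fell without knockdown replicate 3. Single-gene calls were lost for Mvd (0.0178 to 0.0968) without control replicate 1 or 2 or knockdown replicate 1 or 2, Idi1 (0.0206 to 0.0692) without control replicate 1 or knockdown replicate 1 and Fdps (0.0149 to 0.0538) without knockdown replicate 1. Lost as well were the calls of Fdps with array median scaling (0.0546), Mvd with array median scaling, no detection filter or treat (0.0704 to 0.0994), Idi1 with array median scaling or row 1 alone (0.0593 to 0.0684) and Stard4 with row 1 alone (0.0559).

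Cell cycle genes lay slightly lower as groups, with few single genes past the threshold. Of 31 measured DNA replication and G1/S genes, 0 rose by limma (1 at an unadjusted p under 0.05) and 3 fell, and adjusted over the list alone 0 rose and 5 fell. Those that fell were Cdc6 (-0.72, SE 0.15), Cdc45 (-0.63, SE 0.12) and E2f2 (-0.49, SE 0.11), while Ccne1 at 0.59 did not pass. A call was gained by Ccne1 with normexp, quantile normalization, an intensity trend or array weights (0.00818 to 0.725). The replication list lay lower (median -0.27, from -0.50 to -0.19 over 21 alternatives; camera adjusted p = 0.000164; adjusted p = 0.672 with an estimated correlation), with camera adjusted p = 0.000173 with the row block and 6.49e-05 within row 1 (median -0.34). Of 27 measured mitosis genes, 0 rose by limma (1 at an unadjusted p under 0.05) and 3 fell, and adjusted over the list alone 0 rose and 5 fell. The falls were Nusap1 (-0.53, SE 0.09), the proliferation marker Mki67 (-0.50, SE 0.09) and Ccnb2 (-0.49, SE 0.10). The mitosis list lay lower (median -0.30, from -0.53 to -0.20 over 21 alternatives; camera adjusted p = 0.00109; adjusted p = 0.672 with an estimated correlation), with camera adjusted p = 0.00181 with the row block and 0.000881 within row 1 (median -0.32). Of the replication genes none rose and none fell with any array left out except control replicate 3. Of the mitosis genes none rose and none fell with any array left out. Gene calls were lost for Cdc45 (0.0549 to 0.0988), Nusap1 (0.0518 to 0.108), Mki67 (0.0568 to 0.103) and Ccnb2 (0.0693 to 0.169) with any array left out and Cdc6 (0.0307 to 0.122) and E2f2 (0.0363 to 0.173) with any array left out except control replicate 3. Further losses were those of Cdc6, Cdc45, E2f2, Nusap1, Mki67 and Ccnb2 with array median scaling, no detection filter, treat or row 1 alone (0.0806 to 0.43).

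Few glycolysis and no ribosomal protein genes passed the threshold. Of 25 measured glycolysis and hypoxia genes, 0 rose by limma (1 at an unadjusted p under 0.05) and 1 fell, and adjusted over the list alone 0 rose and 1 fell. The fall was that of Ankrd37 (-1.27, SE 0.22), while Aldoc at 1.18 and Ddit4 at -0.84 did not pass. Calls were gained by Aldoc with normexp or an intensity trend (0.0246 to 0.292) and Ddit4 with an intensity trend, array weights, the slide row as a block or without knockdown replicate 3 (0.0228 to 0.384). The glycolysis and hypoxia list lay lower (median -0.25, from -0.48 to -0.14 over 21 alternatives; camera adjusted p = 0.016; adjusted p = 0.675 with an estimated correlation), with camera adjusted p = 0.00322 with the row block and 0.000275 within row 1 (median -0.31). That call ended without control replicate 3 (0.112), knockdown replicate 1 (0.14) or knockdown replicate 2 (0.149) and with normexp with quantile normalization (0.0931) or quantile normalization (0.154). Adjusted p spanned 8.2e-06 to 0.154 over 21 alternatives. Of 34 measured ribosomal protein genes, 0 rose by limma (0 at an unadjusted p under 0.05) and 0 fell by limma (0 at an unadjusted p under 0.05), and adjusted over the list alone 0 rose and 0 fell. Rps24 at -0.31 did not pass. The ribosomal list lay lower (median -0.11, from -0.34 to 0.00333 over 21 alternatives; camera adjusted p = 0.0354; adjusted p = 0.675 with an estimated correlation), with camera adjusted p = 0.0476 with the row block and 0.0017 within row 1 (median -0.19), though its median turned to 0.00333 with normexp with quantile normalization and its test turned, with a median of -0.00169, with quantile normalization. Its call ended without control replicate 1 (0.142), knockdown replicate 1 (0.122) or knockdown replicate 2 (0.428) and with array median scaling (0.237) or the filter of all 6 arrays (0.119). Adjusted p spanned 0.0017 to 0.757 over 21 alternatives. Of the glycolysis genes none rose and none fell with any array left out except knockdown replicate 3 and none rose and 3 fell without knockdown replicate 3. The gene call was lost for Ankrd37 (0.0124 to 0.0804) with any array left out except knockdown replicate 3. Also lost were the calls of Ankrd37 with no detection filter (0.0658).

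A few histone genes changed. Of 19 measured histone genes, 3 rose and 1 fell, and adjusted over the list alone 4 rose and 3 fell. The rises were H1f2 (1.34, SE 0.13), H2bc4 (1.32, SE 0.14) and H2aw (0.59, SE 0.13), and H2az2 (-0.57, SE 0.09) fell. The histone list did not pass the set test (median -0.15, camera adjusted p = 0.913; adjusted p = 0.958 with an estimated correlation), nor with the row block (0.705) or within row 1 (0.518). The sign of its mean (0.02) differed from that of its median and test. With arrays omitted, 2 rose and none fell without control replicate 1 or knockdown replicate 1 or 2, 3 rose and none fell without control replicate 2 and 2 rose and 3 fell without control replicate 3. Single-gene calls were lost for H2aw (0.0872 to 0.14) with any array left out and H2az2 (0.0444 to 0.0998) without control replicate 1 or 2 or knockdown replicate 1 or 2. Other calls lost were those of H2aw and H2az2 with array median scaling, no detection filter, treat or row 1 alone (0.0795 to 0.722), H1f2 with array median scaling (0.0713) and H2bc4 with array median scaling or row 1 alone (0.0559 to 0.0845).

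Integrated stress response genes lay lower as a group, and p53 targets went both ways. Of 26 measured genes of the integrated stress and unfolded protein responses, 2 rose and 4 fell, and adjusted over the list alone 2 rose and 5 fell. The cystathionine lyase gene Cth was at least 7.11-fold higher (adjusted p = 0.000171) and not well above background on any control array, with a fitted change of 1.17 with normexp, and Trib3 (-0.91, SE 0.16), Nupr1 (-0.80, SE 0.14) and Ddit3 (-0.78, SE 0.12) fell. Past the threshold too, and named after their values were seen, were Calr (0.68, SE 0.12) and Hsp90b1 (-0.48, SE 0.11). The list lay lower (median -0.30, from -0.53 to -0.23 over 21 alternatives; camera adjusted p = 0.016; adjusted p = 0.672 with an estimated correlation), with camera adjusted p = 0.00842 with the row block and 0.00213 within row 1 (median -0.36). Its call ended without knockdown replicate 2 (0.149) and with quantile normalization (0.0999) or array median scaling (0.395). Adjusted p spanned 0.000766 to 0.395 over 21 alternatives. Of 21 measured p53 targets, 3 rose and 3 fell, and adjusted over the list alone 4 rose and 7 fell. Among them Phlda3 (0.90, SE 0.11) rose, and Bbc3 (-1.12, SE 0.11), Trp53inp1 (-0.70, SE 0.14) and Tigar (-0.64, SE 0.13) fell. Also past the threshold, and named after their values were seen, were Cdkn1a (0.59, SE 0.10) and Bax (0.60, SE 0.10). That list did not pass the set test (median -0.30, camera adjusted p = 0.289; adjusted p = 0.672 with an estimated correlation), nor with the row block (0.254) or within row 1 (0.0825). With normexp the change was smaller, with Tigar at -0.30. Of the stress response genes 1 rose and none fell without control replicate 1 or knockdown replicate 1, 1 rose and 1 fell without control replicate 2 or knockdown replicate 2 and 1 rose and 4 fell without control replicate 3. Of the p53 targets 1 rose and 1 fell without control replicate 1 or knockdown replicate 1, 2 rose and 1 fell without control replicate 2 or 3 and 1 rose and 3 fell without knockdown replicate 3. Gene calls were lost for Trp53inp1 (0.0235 to 0.109) and Calr (0.0409 to 0.083) with any array left out except knockdown replicate 3, Tigar (0.0241 to 0.157) and Cdkn1a (0.0475 to 0.0961) with any array left out except knockdown replicate 2, Hsp90b1 (0.0489 to 0.142) with any array left out except control replicate 3, Trib3 (0.0192 to 0.0993) and Nupr1 (0.0335 to 0.0993) without control replicate 1 or 2 or knockdown replicate 1 or 2, Bax (0.0383 to 0.0917) without control replicate 1 or knockdown replicate 1, 2 or 3 and Ddit3 (0.0215 to 0.0755) without control replicate 1 or knockdown replicate 1. Calls also ended for Cdkn1a with the mean over probes (0.22, adjusted p = 0.222), within a range of 0.00108 to 0.726 over 21 alternatives and Tigar with the mean over probes (-0.61, adjusted p = 0.197) or an intensity trend (-0.64, adjusted p = 0.106), within a range of 0.00513 to 0.259 over 21 alternatives. Further calls lost were those of Nupr1, Ddit3, Trp53inp1, Tigar, Calr, Hsp90b1, Cdkn1a and Bax with array median scaling, no detection filter, treat or row 1 alone (0.0515 to 0.726), Trib3 with array median scaling, no detection filter or treat (0.0588 to 0.0707) and Phlda3 with array median scaling or row 1 alone (0.0571 to 0.498).

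Immediate early and interferon genes went both ways. Of 17 measured immediate early genes, 2 rose and 2 fell, and adjusted over the list alone 5 rose and 6 fell. The rises were Jun (0.95, SE 0.11) and Klf4 (0.51, SE 0.11), and the falls were Egr1 (-2.92) and Junb (-1.28, SE 0.11). The list did not pass the set test (median -0.01, camera adjusted p = 0.932; adjusted p = 0.958 with an estimated correlation), nor with the row block (0.989) or within row 1 (0.861). Of 19 measured interferon response genes, 2 rose and 3 fell, and adjusted over the list alone 7 rose and 4 fell. Among them Oas3 (0.94, SE 0.15) rose, though not with normexp (0.32, adjusted p = 0.144; adjusted p from 0.00271 to 0.453 over 21 alternatives), and Ifit2 (-1.03, SE 0.20), Ifi47 (-0.78, SE 0.12) and Stat2 (-0.65, SE 0.10) fell. Past the threshold too, and named after its value was seen, was Ddx58 (0.43, SE 0.09). The interferon list did not pass the set test (median 0.20, camera adjusted p = 0.492; adjusted p = 0.672 with an estimated correlation), nor with the row block (0.379) or within row 1 (0.566). With normexp the sizes shrank, with Ifit2 at -0.69, Jun at 0.57 and Klf4 at 0.34. Of the immediate early genes 1 rose and 2 fell without control replicate 1 or 2 or knockdown replicate 1 or 2 and 1 rose and 3 fell without knockdown replicate 3. Of the interferon genes none rose and 1 fell without control replicate 1 or 2, 1 rose and 1 fell without control replicate 3 or knockdown replicate 2 and none rose and none fell without knockdown replicate 1. Omission of an array ended the calls of Ddx58 (0.0776 to 0.135) with any array left out, Klf4 (0.0476 to 0.149) with any array left out except control replicate 3, Oas3 (0.0123 to 0.0712) and Ifit2 (0.0453 to 0.114) with any array left out except knockdown replicate 2, Stat2 (0.0314 to 0.0893) without control replicate 2 or 3 or knockdown replicate 1 or 2 and Ifi47 (0.023 to 0.0782) without control replicate 1 or knockdown replicate 1 or 2. Other settings ended the calls of Oas3 with quantile normalization (0.75, adjusted p = 0.142), within a range of 0.00271 to 0.453 over 21 alternatives. Lost as well were the calls of Klf4, Oas3, Stat2 and Ddx58 with array median scaling, no detection filter, treat or row 1 alone (0.0507 to 0.822), Ifi47 with array median scaling, no detection filter or treat (0.0542 to 0.129), Jun with array median scaling or row 1 alone (0.0526 to 0.437) and Ifit2 with no detection filter, treat or row 1 alone (0.0867 to 0.0894).

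Lysosomal genes rose more often than they fell. Of 26 measured lysosomal genes, 5 rose and 2 fell, and adjusted over the list alone 7 rose and 2 fell. The cathepsin genes Ctsl (1.28, SE 0.16) and Ctsz (0.87, SE 0.11) and the glucuronidase gene Gusb (0.80, SE 0.13) rose, and Ctsb (-0.60, SE 0.12) fell. Also past the threshold, and named after their values were seen, were Glb1 (0.48, SE 0.11), Neu1 (0.50, SE 0.11) and Npc1 (-0.58, SE 0.11). The list lay higher (median 0.09, from -0.15 to 0.19 over 21 alternatives; camera adjusted p = 0.0329; adjusted p = 0.672 with an estimated correlation), with camera adjusted p = 0.0476 with the row block and 0.209 within row 1 (median 0.19), though its median turned to -0.15 with array median scaling, where the median of all genes was -0.27. Its call ended without control replicate 1 (0.0714), control replicate 3 (0.0635), knockdown replicate 1 (0.0918) or knockdown replicate 3 (0.149) and with array median scaling (0.395), no detection filter (0.122) or slide row 1 alone (0.209). Adjusted p spanned 0.00119 to 0.395 over 21 alternatives. With arrays omitted, 2 rose and none fell without control replicate 1 or knockdown replicate 1 or 2, 3 rose and none fell without control replicate 2 or knockdown replicate 3 and 2 rose and 1 fell without control replicate 3. Single-gene calls were lost for Glb1 (0.0953 to 0.184), Neu1 (0.0528 to 0.162) and Npc1 (0.0524 to 0.125) with any array left out, Ctsb (0.0411 to 0.158) with any array left out except control replicate 3 and Gusb (0.0319 to 0.0756) without control replicate 1 or 3 or knockdown replicate 1 or 2. Calls also ended for Gusb with the mean over probes (0.62, adjusted p = 0.0695), within a range of 0.000526 to 0.614 over 21 alternatives and Npc1 with normexp with quantile normalization (-0.35, adjusted p = 0.0639) or quantile normalization (-0.70, adjusted p = 0.0954), within a range of 0.00777 to 0.328 over 21 alternatives. Further losses were those of Gusb, Ctsb, Glb1, Neu1 and Npc1 with array median scaling, no detection filter, treat or row 1 alone (0.0659 to 0.787) and Ctsl and Ctsz with array median scaling or row 1 alone (0.072 to 0.54).

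Antigen presentation genes that changed fell, and adhesion genes went both ways. Of 16 measured antigen presentation genes, 0 rose by limma (1 at an unadjusted p under 0.05) and 4 fell, and adjusted over the list alone 0 rose and 5 fell. The falls were Tap1 (-0.93, SE 0.16, well above background on 2 of 3 knockdown arrays), Psmb9 (-0.52, SE 0.09), Tapbp (-0.51, SE 0.10) and H2-T10 (-0.45, SE 0.10). The list did not pass the set test (median -0.01, camera adjusted p = 0.592; adjusted p = 0.736 with an estimated correlation), nor with the row block (0.711) or within row 1 (0.669). Of 19 measured adhesion and surface signalling genes, 2 rose and 3 fell, and adjusted over the list alone 3 rose and 4 fell. The rises were Icam1 (1.52, SE 0.20) and Selplg (1.12, SE 0.16), and Itgb7 (-1.25, SE 0.27) and Itga4 (-0.92, SE 0.11) were among the falls. Past the threshold too, and named after its value was seen, was Itgb1 (-0.47, SE 0.10). The adhesion list did not pass the set test (median 0.09, camera adjusted p = 0.717; adjusted p = 0.749 with an estimated correlation), nor with the row block (0.726) or within row 1 (0.518). With normexp the changes were smaller, with Icam1 at 0.69 and Tap1 at -0.33. Of the antigen presentation genes none rose and none fell without control replicate 1 or 2 or knockdown replicate 1, none rose and 1 fell without control replicate 3 or knockdown replicate 3 and none rose and 2 fell without knockdown replicate 2. Of the adhesion genes 2 rose and 1 fell without control replicate 1 or 2 or knockdown replicate 2 and 1 rose and 1 fell without knockdown replicate 1. Gene calls ended by leaving out an array were those of Tapbp (0.051 to 0.108), H2-T10 (0.0868 to 0.166) and Itgb1 (0.070 to 0.154) with any array left out, Psmb9 (0.0475 to 0.126) with any array left out except knockdown replicate 2, Itgb7 (0.0193 to 0.133) with any array left out except knockdown replicate 3, Tap1 (0.0328 to 0.0855) without control replicate 1 or 2 or knockdown replicate 1 and Selplg (0.0198 to 0.0579) without knockdown replicate 1. Other settings ended the calls of H2-T10 with quantile normalization (-0.42, adjusted p = 0.0509), within a range of 0.0125 to 0.477 over 21 alternatives, Itgb7 with quantile normalization (-1.17, adjusted p = 0.0512), within a range of 0.00381 to 0.133 over 21 alternatives and Tap1 with an intensity trend (-0.93, adjusted p = 0.0934), within a range of 0.00572 to 0.0934 over 20 alternatives. Also lost were the calls of Psmb9, Tapbp, H2-T10 and Itgb1 with array median scaling, no detection filter, treat or row 1 alone (0.103 to 0.477), Tap1 and Itgb7 with no detection filter, treat or row 1 alone (0.0574 to 0.112), Itga4 with array median scaling (0.0523), Selplg with array median scaling or row 1 alone (0.0604 to 0.236) and Icam1 with row 1 alone (0.0664).

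**Figure D4:**
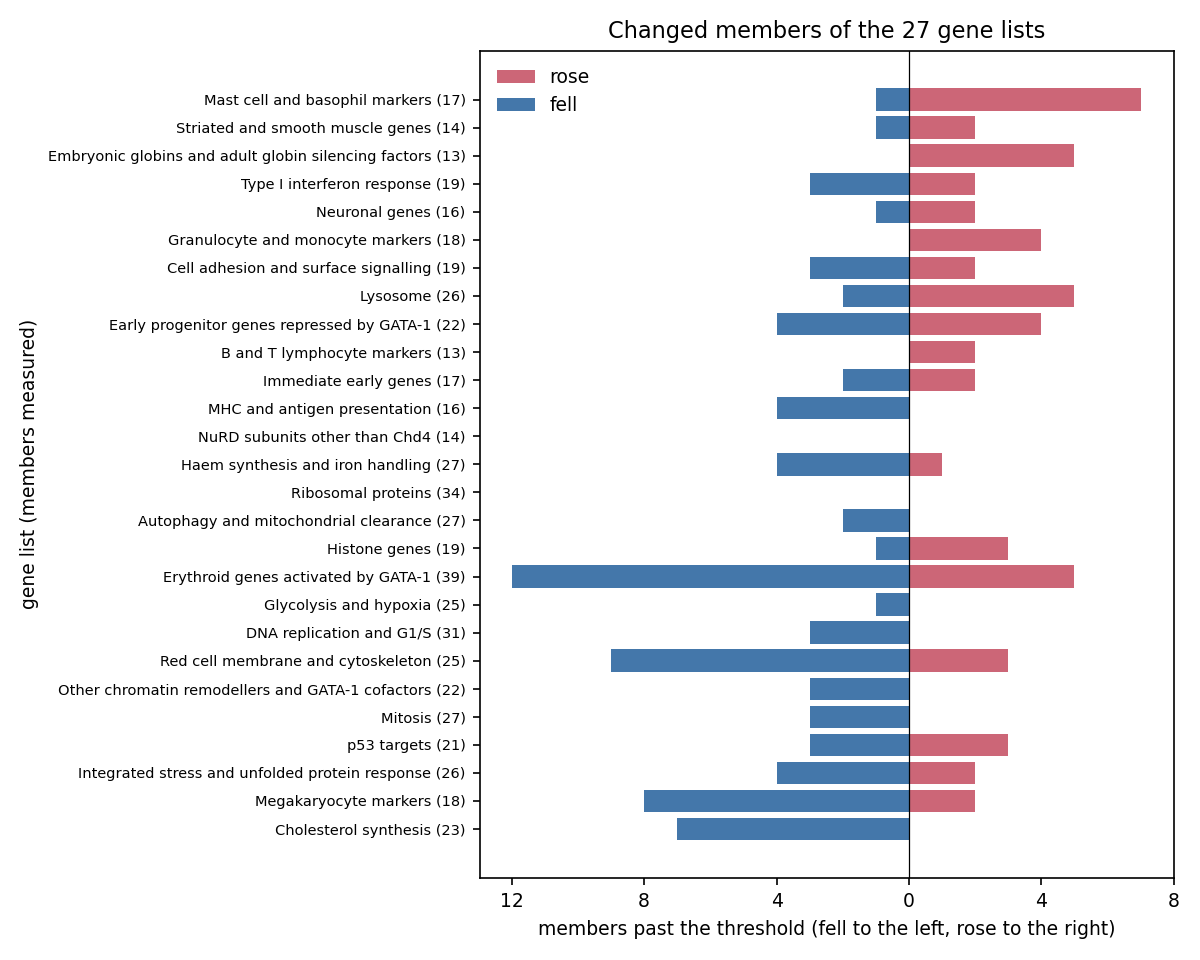
Bars count the members of each of the 27 gene lists that rose (red, to the right) or fell (blue, to the left) past the threshold, with the members measured in parentheses and lists ordered by median change. The longest red bar is that of the mast cell and basophil markers (7 of 17) and the longest blue bar that of the genes activated by GATA-1 (12 of 39).

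Together 14 of the 27 lists passed the set test, 4 higher and 10 lower. With an estimated correlation 0 lists passed by limma's camera (1 of 27 at an unadjusted p under 0.05, the mast cell and basophil markers), and with fry, which tests whether a list's genes move 1 way on balance, 7 did. Without knockdown replicate 2, 8 lists passed, and 14 did with the slide row as a block and 14 within row 1.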

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

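The tests in this part were chosen only after the result was seen, except the counts over other splits of the arrays.

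Control signals that the comparison does not use stood above the control arrays. The negative control spots had a higher mean signal on all 3 knockdown arrays than on any control array, by more than the range of the control arrays on replicates 2 and 3. On knockdown replicate 2, a pair of added E1A spike-in RNAs, which no cell makes, had log2 signals of 4.31 and 5.66, against at most 2.87 and 4.99 on the control arrays. The negative control spots had mean signals of 29.2, 30.4 and 34.2 on knockdown replicates 1 to 3, against at most 28.7. The medians of the same spots were 27.9, 30.1 and 28.0 for knockdown replicates 1 to 3, against 26.5 to 28.3 on the control arrays. On knockdown replicate 1 the dimmer of those 2 spike-ins was at 2.92.

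Knockdown replicate 2 also had the highest share of probes well above background, 74.0%. All 3 spike-ins in the dim range, used to test for non-specific signal or background on that array, were higher there than on the other 5 arrays, and the 7 brighter ones were not. Their gaps to the next array were 1.55, 1.39 and 0.67 on the log2 scale, against ranges of 1.57, 0.61 and 0.49 over the other 5 arrays, so that 2 exceeded that range. More transcription in that sample alone would not raise an added RNA, so these gaps argue against it as the whole cause. Non-specific signal at the dim end is consistent with these values, and what produced it stays open.

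Rises made up 73.9% of genes changed at least 2-fold; without knockdown replicate 2 in both the filter and the fit, 66.2% were rises (95% exact binomial interval 62.5 to 69.7). With array median scaling 59.7% were rises (95% exact binomial interval 56.3 to 63.0). These 2 values argue against that array and against the scaling, each as the whole cause, over intervals of genes that are not independent. The explanation that dim genes can rise and hardly fall at the scanner's lower limit was tested on the brighter genes: with the genes parted at the median control signal, 51.1% were rises (95% exact binomial interval 45.0 to 57.2) in the brighter part, a split that favours falls, and with the genes parted by the mean over all 6 arrays, a split that favours rises, 60.8% were. Because the 2 splits lean opposite ways, that limit cannot be told apart from an effect of the loss of Mi2β on repressed genes, a hypothesis, and a higher background on the knockdown arrays also stays open.

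The embryonic globin genes Hbb-bh1, Hbb-y and Hba-x rose, and cross-hybridisation from adult globin RNA was weighed as the source. The adult globin with the largest change, Hbb-bt, rose by 0.81 (upper 95% limit 1.09), below the lower limit of 3.05 for the smallest embryonic rise, that of Hba-x. This argues against adult globin RNA as the whole source if the bright adult probes respond fully. Shared signal among the embryonic genes was not tested. An effect of Mi2β on embryonic globin genes may account for the rise, as a hypothesis from the same data.

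The 10 splits of the 6 arrays into 3 and 3 are too few for a share under 0.05. The real split gave 2115 changed genes (1 of 10 splits reached that, and the highest other split gave 43), 758 changed at least 2-fold (1 of 10, highest other 43) and 14 lists (1 of 10, highest other 13). The split with 13 lists had 0 changed genes, so the list count hardly sets the real grouping apart.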

How the results depend on the processing

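Slide row alternatives were chosen after seeing the data, and the others were planned. The fall of Chd4 kept its direction and call under all 21 alternatives (-1.54 to -1.24). The genes changed, 2115 as reported, numbered 3571 with normexp and quantile normalization, 831 with array median scaling, 993 with no detection filter, 3306 with an intensity trend, 4729 with array weights, 1002 with treat at a 1.2-fold minimum and 720 within slide row 1. They numbered 813 to 1579 with single arrays left out, and 1801 to 2743 under the remaining alternatives, apart from the replicate block. Of the 2115 genes, 633 were also called in the same direction with array median scaling and 936 with no filter. At least 2-fold, 758 genes became 429 with normexp, 600 to 816 with single arrays left out and 593 to 954 otherwise. The lists past the set test, 14 as reported, numbered 8 with quantile normalization, 8 to 14 with single arrays left out and 10 to 15 otherwise. Without the filter 34938 genes were tested, treat asks for a larger change, and leaving out arrays leaves fewer samples. Other causes were not tested. Array median scaling moved the median change of all genes from -0.03 to -0.27, and changes under it are relative to that shift.

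Ribosomal protein genes turned direction with normexp (median 0.00333, adjusted p = 0.711) and with quantile normalization (test higher, median -0.00169, adjusted p = 0.757), and the cause was not tested. Of the 14 lists past the test, 6 kept their call under all 21 alternatives: cholesterol synthesis, DNA replication, mitosis, chromatin cofactors, mast cell and megakaryocyte. With an estimated correlation none of these 6 passed (adjusted p from 0.29 to 0.672), and with fry DNA replication did not (adjusted p = 0.0945). Of 173 genes examined singly besides Chd4, 138 were past the threshold. Of these 0 changed sign under the alternatives, 50 kept their call under every alternative that measured them, and 68 did with each array left out in turn. Of the other 35, 10 changed sign and 16 passed under at least 1 alternative.

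The replicate numbers were not shown to pair the samples. Deviations of same-numbered arrays correlated at 0.21, -0.32 and 0.13, and 2 of 6 arrays correlated best with their own number. So few values cannot exclude pairing, and same-numbered arrays lay side by side in a slide row. With the replicate block 685 genes changed, 71 of the 138 calls of genes examined singly ended, and so did those of 3 lists, the red cell membrane (adjusted p = 0.0541), ribosomal (adjusted p = 0.0647) and lysosomal genes (adjusted p = 0.0611). The slide as a block was not run, since 1 slide held all arrays. Dim genes limit the measurement: 26090 of 55681 probes were well above background on all 6 arrays.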

Other observations

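The test of the Ift family under the alternatives, the test without knockdown replicate 2, that of fallen genes and that of all adjacent pairs were chosen only after a result was seen, as were the pairs and genes named in this part.

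Intraflagellar transport genes, which build cilia, were among the falls. Of 13 measured genes with the stem Ift, 6 fell: Ift122 by 1.52, Ift172 by 0.99, Ift20 by 0.67, Ift27 by 0.64, Ift80 by 0.60 and Ift57 by 0.47 on the log2 scale. In all 10 of the 13 lay below 0. The hypothesis was that some family holds more changed genes than the genes tested, and of 462 tests of a stem and a direction only this one passed (Fisher's exact test, 46.2% against 5.98% of all genes, adjusted p = 0.0246). Family members can be regulated together, so they are not independent. Over 21 alternatives 2 to 9 Ift genes fell, and the family passed under 7 of them (adjusted p from 0.00302 to 1). It did not with any single array left out (adjusted p from 0.0699 to 1), with array median scaling (adjusted p = 0.842), with the slide row as a block (adjusted p = 0.617) or within row 1 (adjusted p = 1), so the excess depends on the setting. The fall of Ift122 was over 1.5 times smaller with normexp. With arrays left out in turn, calls were lost (adjusted p range) for Ift57 (0.0588 to 0.181) with any array left out, Ift27 (0.0332 to 0.114) with any array left out except control replicate 1, Ift80 (0.0476 to 0.122) with any array left out except knockdown replicate 3 and Ift20 (0.0355 to 0.088) without control replicate 2 or 3 or knockdown replicate 1 or 3. Calls also ended for Ift57 with the mean over probes (-0.47, adjusted p = 0.0509), within a range of 0.00984 to 0.451 over 21 alternatives. Other calls lost were those of Ift20, Ift27, Ift80 and Ift57 with array median scaling, no detection filter, treat or row 1 alone (0.0704 to 0.451).

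The hypothesis that genes that rose at least 2-fold lie beside each other was tested on 12969 genes in the RefSeq order of GRCm38.p6. Leaving out pairs that overlap or share a name stem, 20 adjacent pairs both rose, against a mean of 12.1 in 10000 shuffles within 10 bins of the control level (permutation p = 0.0205, adjusted p = 0.0273 over 4 such tests). Without knockdown replicate 2 there were 17 pairs against 9.60 (permutation p = 0.0201). Genes that fell showed 2 pairs against 1.24 (permutation p = 0.355). With all adjacent pairs counted, 37 rose together against 16.2 (permutation p = 1e-04, the smallest the shuffles can give). The pairs with the largest smaller change were Cpne6 (3.42, SE 0.13) with Nrl (3.90, SE 0.29), Adcy4 (2.55, SE 0.23) with Ripk3 (4.45, SE 0.44, well above background on 1 of 3 control arrays), and Rasal1 (2.21, SE 0.10) with Dtx1 (at least 30.2-fold higher). With normexp the sizes shrank, with Adcy4 at 1.65 and Ripk3 at 1.89. Regional release of repression is a candidate explanation for the p of 0.0205, which local co-expression unrelated to Mi2β could also give.

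Genes that rose at least 2-fold were not shown to gather on a chromosome. The largest share was on X, 23 of 428 genes (5.37%) against 3.41% of all, with a Fisher's exact p = 0.0293 that failed the correction (adjusted p = 0.342, the lowest over 20 chromosomes).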
